A study of Mus musculus with 2 samples.

How the data were processed

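H3K4me3 was profiled by ChIP-seq in neural tube tissue of mouse embryos of strain B6NTac;B6NCrl/Lap at 14.5 days, in 2 biological replicates made from pools of 24 and 34 embryos of both sexes, per the labels. Replicate 1 joined 2 technical replicates and replicate 2 had 1. All samples form 1 group, and the labels name the replicates. What differs between the pools is biological and technical at once.

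The authors deposited 4 peak lists in narrowPeak format on mm10. Per the deposited notes beside the files, the peaks of replicate 1 were called on its filtered alignment against a control file, the peaks of replicate 2 against that control and an additional one, and the pooled peaks on both replicates together against both controls. The replicated list was derived from the other lists, and the rule for keeping a peak is not given in the sources used here. Neither are the aligner, the peak caller and their versions. A test on the files showed that all 21022 replicated peaks were pooled peaks with unchanged bounds, that 19791 of them overlapped a peak of each replicate, and that 1175 overlapped no peak of replicate 1. The signal of a peak, the unit used for height here, is the value in the signal column that the authors deposited with each peak. It was taken as an enrichment from the definition of the format, since the notes do not name its scale, and every fold or log2 ratio of signals depends on that reading. It is never below 1.26 in these lists. The deposited lists also give −log10 of the p-value and of the q-value per peak, which were used only as alternatives, and the lowest −log10 p-value in any list was 2.03. Signals were used to describe, rank and filter peaks, and a ratio of signals between replicates compares lists called against different controls. The number of reads is not in the files used here, so no interval that needs depth is given; exact binomial intervals (Clopper-Pearson, 95%) refer to counts of peaks or genes and cover counting error only.

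Peaks were compared with GENCODE release M21 on GRCm38, the assembly of mm10, and 0 lists had a peak beyond the end of a chromosome. TSSs were the starts of all annotated transcripts. A gene was called marked when a peak overlapped the 1000 bp either side of any of its TSSs, its signal was the highest among those peaks, and 21938 protein-coding genes on chromosomes 1 to 19, X and Y were scored. A peak so near to a TSS can belong to a neighbouring gene: 20.7% of the marked genes share their domain with another protein-coding gene. Peaks of a list within 1000 bp of each other were merged into domains, a gene took the widest domain that touched its TSS windows, and the widest 5% of the domains of a list were called broad. That width was 4446 bp for the replicated list, 4065 bp for replicate 1 and 4646 bp for replicate 2. Peaks on unplaced contigs were left out of comparisons with genes.

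Peaks counted as shared when they overlapped by at least 1 bp, and chance overlap came from 100 circular shifts of a list within each chromosome. The 24 gene lists were fixed before the data were examined. So were the tests and the alternatives, except those said to be added or chosen after the data or results were seen. Lists were compared with the other protein-coding genes, and for broad domains with the other marked genes, by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the 24 lists and a threshold of 0.05. Promoter sequence was allowed for by simulating 10000 random lists matched on CpG density in 20 bins. CpG density was the highest within 500 bp of any TSS of a gene. Each simulated gene was marked or broad at random, independently. The chance was the share among the other genes (for broad domains, the other marked genes) of its bin. The smallest adjusted p of this simulation is 6.86e-04 for broad domains and 0.00120 for having a peak. Median widths were compared by two-sided permutation tests with 100000 resamples. Replicates were compared at genes by the log2 ratio of their signals, with 10000 random lists matched on mean signal. The random seed was 1.

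The genes named were set by rule: the protein-coding genes at the widest domains up to at least 20; from each list the pair with the widest domains, the gene with the highest mean signal, and up to 2 genes without a peak in alphabetical order; the 5 largest and 5 smallest replicate ratios among genes above the median mean signal; the genes nearest to the 5 strongest unshared peaks of each replicate; and all members of a group of up to 5 that stood apart from the rest of their list. Genes outside the rule are said to be chosen after their values were seen.

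The alternatives were a -log10 q of at least 2, a signal of at least 5, windows of 500 and 2500 bp, overlaps of 50%, each replicate's own peaks, the pooled peaks, no merging or merging within 3000 bp, the widest 1% and 10% or at least 4000 bp as broad, the CpG-matched lists and other values per peak. Basic transcripts, the counting of each domain once per list and the spinal set without genes of secreted ligands were added after the data were seen. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Overlaps were checked against bedtools 2.31.1. Simulated data covered the 21938 genes, with broad domains at 50% of the marked genes of planted lists and 7% elsewhere. Of planted lists 80.8% were called, and of the others 0.263%. The simulated genes were independent, so these rates do not cover lists whose genes share domains, such as the Hox lists. For the permutation test on sets as large as the spinal and forebrain ones, 6% of 1000 simulated sets with no difference and 75.9% of those with a planted shift had a p below the threshold. The number of simulated sets for that test was raised after a first, smaller run was seen.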

Results

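Trimethylation of histone H3 at lysine 4 (H3K4me3), a mark found at active and poised promoters, was mapped by ChIP-seq in the neural tube of mouse embryos at 14.5 days. The series held 1 group with 2 biological replicates, pools of neural tubes from 24 and from 34 embryos of both sexes, so the design offered no contrast between conditions. The comparisons made here were between the replicates, between the peaks and the annotated genes, and between groups of genes within the tissue. The deposited files were 4 peak lists: the peaks of each replicate, the peaks of both replicates pooled, and the pooled peaks that the authors kept as replicated. The lists gave no read counts, so the sequencing depth behind each peak is unknown. Unless another list is named, peaks below are the replicated ones, all positions are on mm10, and the signal of a peak is the value in the signal column that the authors deposited, taken here as an enrichment.

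Both replicates marked nearly the same strong promoters and parted at weak peaks. Replicate 1 had 26748 peaks covering 31.2 Mb, replicate 2 had 28099 peaks covering 37.6 Mb, and 21022 peaks were kept as replicated. Of the replicate 1 peaks, 88.1% overlapped a replicate 2 peak by at least 1 bp (exact 95% interval 87.7 to 88.5%), and of the replicate 2 peaks 72.3% overlapped a replicate 1 peak (71.7 to 72.8%). Random circular shifts of the other list along each chromosome gave 2.58% and 2.42% on average. The peaks without a partner were weak and narrow: their median signal was 3.11 in replicate 1 and 3.21 in replicate 2, against 12.9 and 25.7 for shared peaks, and their median widths were 216 and 266 bp. Under a demand for at least 50% overlap of both peaks the shares were 65.8% and 62.6%. Across the 19791 replicated peaks that overlapped a peak of each replicate, the log2 signals correlated with Pearson's r = 0.926 and Spearman's rho = 0.918. That correlation runs across peaks, which are not independent replicates, and it was 0.727 when replicate 1's own peaks were the positions.

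**Figure D1:**
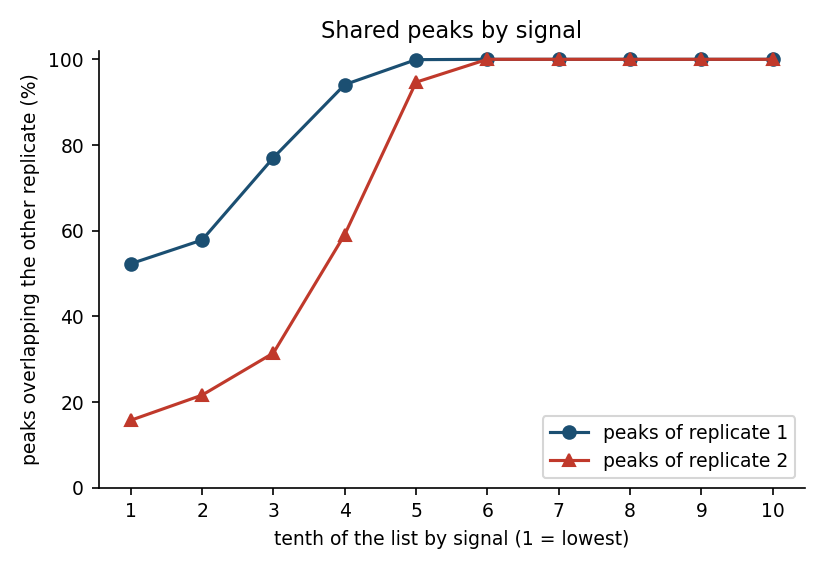
Share of peaks that overlap a peak of the other replicate (percent, y axis) in 10 equal groups of a replicate's own list ranked by signal (x axis, 1 is the lowest); circles are peaks of replicate 1 and triangles peaks of replicate 2. From group 6 upward 100% of the peaks of either list were shared, while in the lowest group 52.3% of the replicate 1 peaks and 15.8% of the replicate 2 peaks were.

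The strongest peaks of 1 replicate with no overlapping peak in the other were still modest. In replicate 1 they lay nearest to Gm10406, Alox8, Zc3h12c, Hspa5 and Kcnh8, with signals from 5.26 to 6.02. In replicate 2 they lay nearest to Pate2, Cacnb2, Srp54c, Hoxa11 and Ldlrad2, with signals from 8.68 to 8.80. The replicate 2 peak near Hoxa11 spanned chromosome 6 from 52247792 to 52248848, and its midpoint was 2510 bp from an annotated Hoxa11 start.

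H3K4me3 in this tissue sat mainly at transcription start sites (TSSs). Of the replicated peaks, 75.8% lay within 1000 bp of an annotated TSS (exact 95% interval 75.2 to 76.4%), against 10.4% on average after circular shifts. Peaks at a TSS had a median signal of 33.0 and a median width of 1790 bp. Peaks elsewhere were weaker, with a median signal of 4.42 for those with a summit in an intron (10.2% of all peaks), 5.89 in an exon (3.21%) and 6.10 between genes (10.7%). Of 21938 protein-coding genes on the main chromosomes, 14240 (64.9%) had a replicated peak within 1000 bp of a TSS. In the replicates' own lists 14236 and 14458 genes had one, with 14167 in common, 69 in replicate 1 alone and 291 in replicate 2 alone.

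Genes of neural progenitors, neurons, glial precursors and the anterior Hox groups almost all carried the mark, and genes of macrophages, liver and gut, red cells, germ cells and olfactory receptors mostly lacked it. The neural progenitor (16 of 16), dorsal patterning (16 of 16), pan-neuronal (20 of 20), glial precursor (15 of 15) and Hox paralogue 1 to 9 (27 of 27) lists had a peak at every member, and 24 of 26 spinal neuron transcription factors did. Housekeeping genes (20 of 20) and chromatin regulators (28 of 28) did too. These 8 lists exceeded the other protein-coding genes, of which about 64.9% had a peak, with adjusted p from 1.04e-04 for the chromatin regulators to 0.00606 for the spinal factors. The tests were two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the 24 gene lists that were fixed before the data were examined. Genes are not replicates, so these p-values and those below describe how the lists differ in these peak sets, and the replicates' own lists serve as the check.

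Promoters rich in CpG are marked in most tissues, and CpG density accounted for much of that excess. By permutation against random lists matched on the CpG density within 500 bp of the TSS, the pan-neuronal list alone of the 8 passed the threshold, at 100% against 83.0% (adjusted p = 0.0106). Another 6 of the 8 lists had a peak at 100% of their genes against matched shares from 93.2% for the neural progenitor list to 98.9% for the chromatin regulators, so near the ceiling that the test had little room to pass. The spinal neuron transcription factors turned direction, at 92.3% against 96.6% (permutation, adjusted p = 0.771). The same matching put the forebrain and midbrain transcription factors below their match, with 18 of 25 genes (72%) marked where their matched lists had 93.3% (permutation, adjusted p = 0.00120).

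The lists with few peaks held the abundant markers of other tissues. Of 13 microglia and macrophage genes, only Irf8, a transcription factor of myeloid cells, had a peak (exact test, adjusted p = 1.46e-04), and Aif1 and C1qa had none. Of 16 liver and gut genes, Foxa1 and Foxa3 had one (exact test, adjusted p = 1.39e-04), and the plasma protein genes Alb and Afp had none. The Foxa3 peak domain also held a TSS of Sympk. Of 15 germline and pluripotency genes, Dazl, Dmrt1 and Dppa3 had a peak (exact test, adjusted p = 0.00147), and Ddx4 and Mael had none. Of 15 erythroid genes, Tal1, Epor, Klf1, Gypa and Nfe2 had a peak (exact test, adjusted p = 0.0262), and Alas2 and Epb42 had none. The erythroid list includes near-identical globin copies such as Hba-a1 and Hba-a2, where reads can be shared, so their lack of a peak is uncertain. Olfr94 and Olfr658 were the marked members of 1093 olfactory receptor genes. Against CpG-matched lists the liver and gut, germline and olfactory receptor lists stayed below, while the microglia list (permutation, adjusted p = 0.532) and the erythroid list (adjusted p = 0.807) did not pass the threshold. The erythroid list even lay above its match, at 33.3% of its genes, by 8.33 percentage points.

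The remaining lists did not pass the threshold for having a peak in the replicated peaks, though several passed in other peak sets. Peaks were found at 12 of 15 ventral patterning genes, with Arx and Dbx1 among those lacking one, and at 12 of 15 neurotransmitter genes, where Dbh and Th, enzymes of catecholamine synthesis, lacked one. Peaks were found at 11 of 12 genes of Hox paralogues 10 to 13, Hoxd12 being the exception, and at 14 of 16 neural crest and peripheral nerve genes, without Hand1 and Phox2b. Mesenchyme and meninges had 15 of 18 (Dcn and Lum without), and endothelium and pericytes had 14 of 16 (Rgs5 and Tie1 without). In mature glia 4 of 12 genes had a peak (exact test, adjusted p = 0.0540), among them Mbp, encoding myelin basic protein, with a signal of 28.1. The widest Mbp domain lay at the 5' end of the annotated gene and covered 1.61% of it. Starts further along the gene were not scored apart. The astrocyte genes Aqp4 and Gfap had no peak. In skeletal muscle 6 of 15 had a peak, Mylpf with the highest signal on a domain that also held a TSS of Tbc1d10b, and Acta1 and Chrna1 had none. In the cardiac list 6 of 14 had a peak, including the calcium channel gene Ryr2, while the myosin genes Myh6 and Myh7 had none. In the epidermal list 7 of 13 had a peak, without Dsg3 and Ivl. In replicate 2's own peaks mature glia genes fell below the other genes (exact test, adjusted p = 0.0453) and Hox paralogues 10 to 13 lay above them (0.0207), and in replicate 1's own peaks the neural crest list lay above (0.0272). At a signal of at least 5 the cardiac (exact test, adjusted p = 0.00359) and skeletal muscle (0.0443) lists fell below, and in the pooled peaks the ventral patterning list lay above (0.0428).

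The widest stretches of H3K4me3 at protein-coding genes covered the Hox clusters, whose genes set position along the body axis. After peaks within 1000 bp of each other were merged into 18359 domains, the widest ran over Hoxb3 to Hoxb9 on chromosome 11 from 96269256 to 96347204, 77949 bp, and the replicates' own domains there were 77963 and 79072 bp wide. The next held TSSs of Hoxa3, Hoxa5, Hoxa6, Hoxa7, Hoxa9, Hoxa10 and the gene model Gm28308 on chromosome 6 from 52200208 to 52241380 (41173 bp; 39560 and 49979 bp in the replicates). Hoxd3, Hoxd4, Hoxd8, Hoxd9 and Hoxd10 shared a domain on chromosome 2 from 74686454 to 74718044 (31591 bp). The replicates differed there: at Hoxd3 the domain was 13329 bp in replicate 1 and 61751 bp in replicate 2. A domain without a protein-coding TSS, at the microRNA gene Mir9-2 and chosen after its value was seen, came next (29746 bp). Hoxc5, Hoxc9 and Hoxc10 shared a domain on chromosome 15 from 102961485 to 102988021 (26537 bp; 26018 and 45561 bp). The naming rule took 22 genes from the widest domains, and all 22 were these genes of the Hox clusters. Some touch their domain through an annotated start while most of the gene lies outside. The domain covered 29.7% of Hoxa3, 26.3% of Gm28308, 16.8% of Hoxd3, 35.5% of Hoxd4 and 41.2% of Hoxc5. Outside the clusters, and chosen after their values were seen, the widest domains at protein-coding genes lay at Ebf3 (24767 bp, chromosome 7 from 137298621 to 137323387), Nr2f2 (22628 bp), Lhx1 (20319 bp, with a TSS of Aatf) and Nfib (19721 bp), which all encode transcription factors apart from Aatf.

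**Figure D2:**
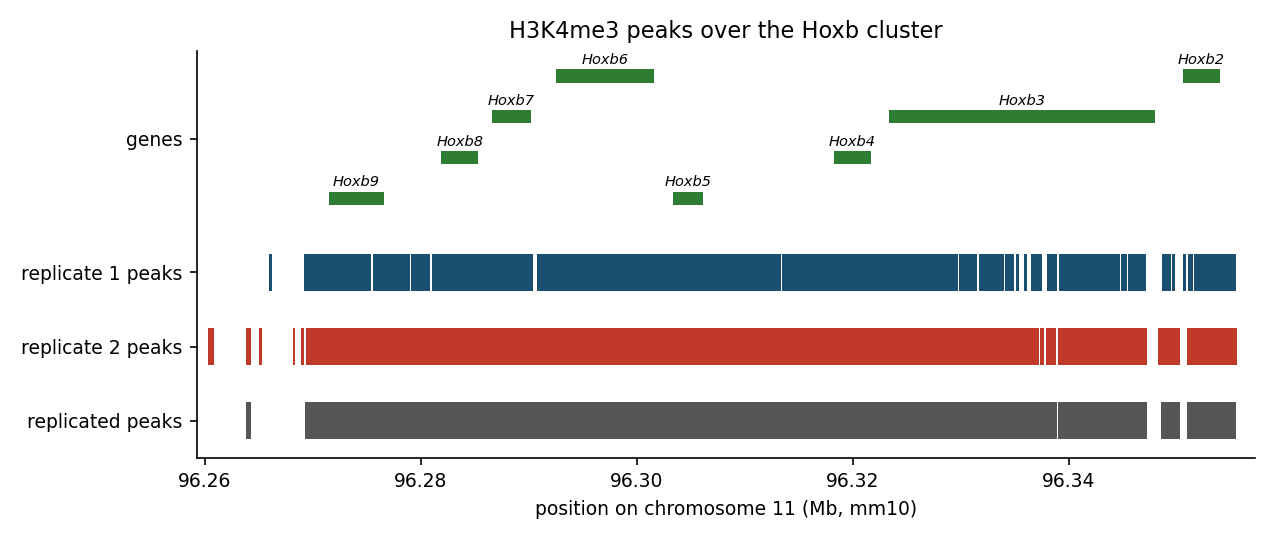
Peaks of replicate 1, replicate 2 and the replicated list (filled blocks) over the Hoxb cluster, with gene bodies above, against position on chromosome 11 in Mb of mm10. Peaks nearly without a break span Hoxb9 to Hoxb3 in both replicates, and the merged replicated domain there is 77949 bp wide.

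Broad domains, the widest 5% of all domains (920 domains of at least 4446 bp), held a larger share of several neural gene lists and of the Hox lists. All nervous system lists together held 64 of the 993 genes in broad domains, so most such genes lay outside them. Among the genes with a TSS peak, 10 of the 24 lists lay in broad domains more often than the other marked genes, of which about 6.98% did, and the same 10 lists passed in each replicate's own peaks. Hox paralogues 1 to 9 led with 23 of 27 genes (exact test, adjusted p = 6.34e-22), followed by neural progenitors with 12 of 16 (1.39e-10), pan-neuronal genes with 14 of 20 (1.84e-11) and Hox paralogues 10 to 13 with 7 of 11 (9.70e-06). Next came the spinal neuron transcription factors with 12 of 24 (9.17e-08), ventral patterning genes with 6 of 12 (2.49e-04), glial precursors with 7 of 15 (1.23e-04), neural crest and peripheral nerve genes with 6 of 14 (6.27e-04) and neurotransmitter genes with 5 of 12 (0.00228). Chromatin regulators had 6 of 28 (exact test, 0.0272), and that call ended against CpG-matched lists (simulation, adjusted p = 0.245), while the other 9 stayed. Without merging of neighbouring peaks the ventral patterning (exact test, adjusted p = 0.146) and neural crest (adjusted p = 0.0516) lists did not pass, and with merging within 3000 bp the chromatin regulators did not (adjusted p = 0.139).

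Named members show how far these domains reached. Among neural progenitor genes, Zic1 had the widest (15120 bp, a domain shared with Zic4; 10450 and 17807 bp in the replicates), then Sox2, a factor that maintains progenitors (9652 bp; 9100 and 11414 bp). Among neuronal genes the widest lay at Myt1l (13749 bp; 13386 and 13822 bp) and at Elavl4, encoding a neuronal RNA-binding protein (12984 bp; 11489 and 12945 bp). The 5 broad neurotransmitter genes were Slc17a6 (12600 bp), the vesicular glutamate transporter, Slc32a1 (11442 bp), the vesicular transporter of GABA and glycine, the GABA-synthesizing enzymes Gad1 (11163 bp) and Gad2 (9051 bp), and Slc6a5 (9021 bp), a glycine transporter. All 5 were broad in both replicates. Nfib and Nfia (19721 and 9772 bp, the latter with a TSS of E130114P18Rik) were widest among glial precursors, and Irx5 and Prdm12 (12519 and 7967 bp) among ventral patterning genes. Tfap2a and Foxd3 (12471 and 9707 bp), both factors of the neural crest, were widest in their list. In replicates 1 and 2 the widths were 19622 and 21275 bp at Nfib, 4927 and 9785 bp at Nfia, and 11788 and 13212 bp at Irx5. They were 4392 and 8729 bp at Prdm12, 8027 and 12160 bp at Tfap2a, and 7281 and 10409 bp at Foxd3. Setd1b and Kdm6b, which encode enzymes that write and erase histone methylation, were widest among chromatin regulators (14245 and 13393 bp), the former on a domain with a TSS of Rhof.

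**Figure D3:**
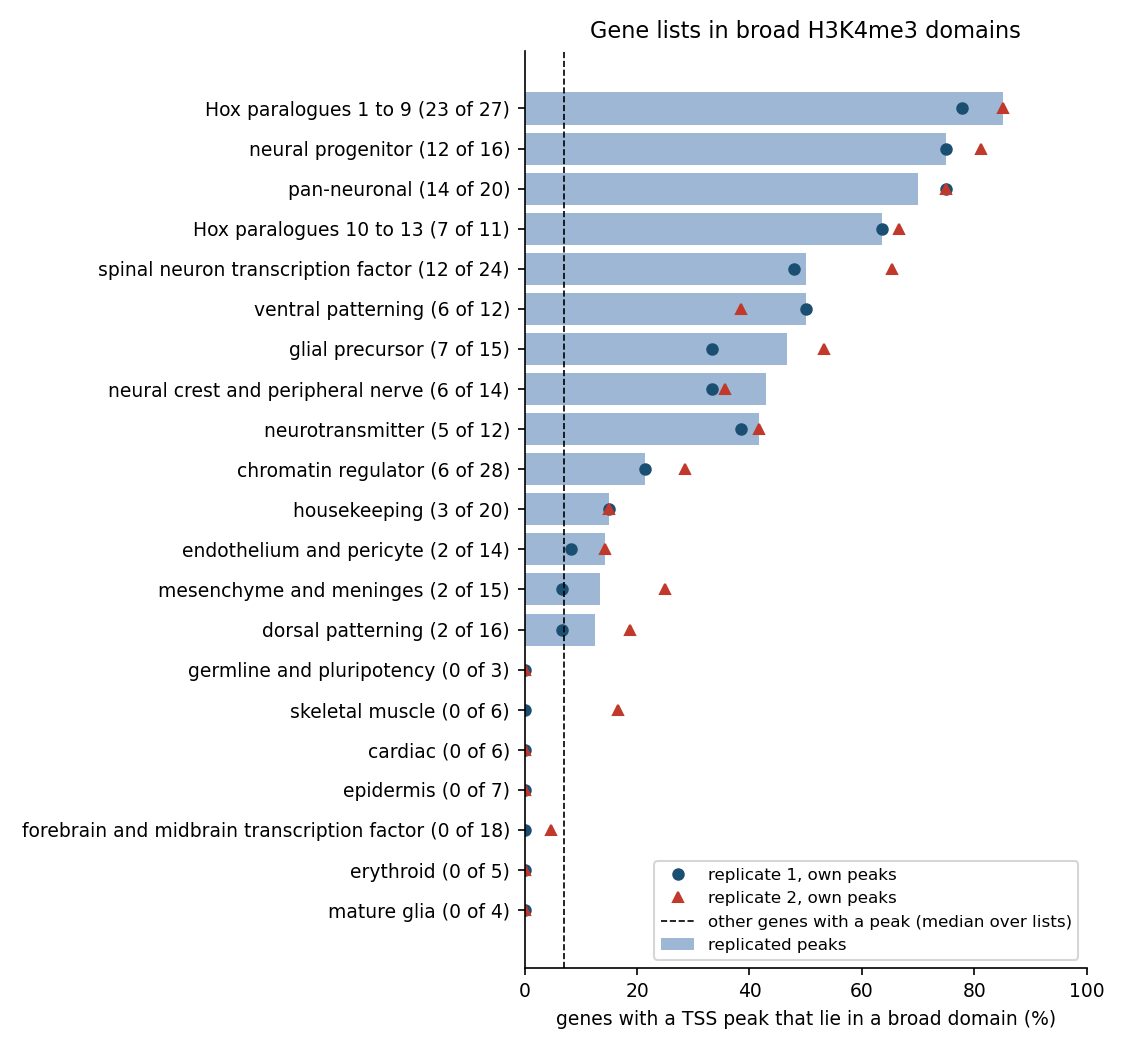
Percent of the genes with a TSS peak that lie in a broad domain (x axis) for each gene list with at least 3 marked genes, with the counts beside the name; bars are replicated peaks, circles replicate 1 and triangles replicate 2, each from its own peaks, and the dashed line is the share among other marked genes. Hox paralogues 1 to 9 reach 85.2% and neural progenitors 75%, while 7 lists have 0 broad genes in the replicated peaks.

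Breadth and height of the mark were only loosely related. Housekeeping genes had a median signal of 48.6, above the 30.2 of neural progenitor genes, and yet a median width of 2956 bp against 5640 bp. Only Tubb5, Eef2 and Tbp among the housekeeping genes lay in a broad domain (3 of 20, exact test, adjusted p = 0.348), and the Tubb5 domain also held a TSS of Mdc1. With the widest 10% of domains called broad, housekeeping genes exceeded the other marked genes by 20.999 percentage points (exact test, adjusted p = 0.0371). Ubc, encoding ubiquitin, had the highest mean signal of that list (58.7 ± 12.4, SD, n = 2) on a domain of 2227 bp. Across the 14240 marked genes, width and signal correlated with Spearman's rho = 0.469, and widths in the replicates' own peaks with rho = 0.909, both across genes. Of the 993 genes in broad domains, 799 were broad in both replicates. No broad domain was found at the marked erythroid (5), skeletal muscle (6), cardiac (6), liver and gut (2), epidermal (7), germline (3), mature glia (4), microglia (1) or olfactory receptor (2) genes. With so few marked genes in each, these counts of 0 did not differ from the other genes (exact test, adjusted p = 1 in each). Mesenchyme (2 of 15: Foxc1 and Foxc2), endothelium (2 of 14: Foxf2 and Egfl7) and dorsal patterning (2 of 16: Ascl1 and Pax3) lay between, with adjusted p from 0.510 to 0.528.

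Transcription factor and patterning genes of the spinal cord carried wider H3K4me3 domains than transcription factor genes of the forebrain and midbrain. The set of 57 spinal genes joined the spinal neuron, dorsal and ventral patterning lists, and was compared with 25 forebrain and midbrain genes. Of the marked genes, 20 of 52 spinal genes lay in a broad domain (38.5%, exact 95% interval 25.3 to 53.0%) and 0 of 18 forebrain genes did (0 to 18.5%; two-sided Fisher's exact test, p = 0.00160). The median widths were 3378 and 1031 bp (permutation test, p = 0.00792). The joined lists were unlike: 12 of 24 marked spinal neuron factors and 6 of 12 ventral patterning genes were broad, but only 2 of 16 dorsal patterning genes were. The labels do not say which levels of the neural tube were dissected, which limits what this difference can mean. The spinal set held 4 genes of secreted ligands, Wnt1, Wnt3a, Gdf7 and Shh; without them 19 of 48 spinal genes were broad (exact test, p = 7.52e-04) and the median width was 3420.0 bp (permutation test, p = 0.00764), an alternative chosen after the data were seen. Both differences had the same direction in each replicate alone, with 19 of 52 against 0 of 19 genes in replicate 1 (exact test, p = 0.00162) and 25 of 55 against 1 of 21 in replicate 2 (p = 8.23e-04). With the widest 1% of domains as the definition of broad, the difference was 21.2 percentage points (exact test, p = 0.0547).

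The widest spinal domains lay at factors of interneuron classes. Lhx1 had 20319 bp (19563 and 20787 bp in the replicates) and Lmx1b 17042 bp (11386 and 17373 bp). Among dorsal patterning genes Ascl1 had 6403 bp and Pax3 5776 bp, and only the Pax3 domain was broad in both replicates. In the forebrain and midbrain list the widest were Barhl2 (2810 bp, with 2667 and 7879 bp in the replicates) and Pitx3 (2035 bp), a factor of midbrain dopamine neurons. The Pitx3 domain covered 14.5% of the gene, at the 3' end of its body. Foxg1, a central factor of the telencephalon chosen after its value was seen, had a domain of 492 bp with a signal of 3.06. Fezf2 and Nkx2-1 had no replicated peak, nor did Otx2, Rax, Six3, Six6 and Tbr1, which were also chosen after the values were seen. Evx1 and Evx2 were the spinal neuron factors without a replicated peak. Having a peak at all was less clearly different, with 52 of 57 spinal (91.2%) and 18 of 25 forebrain genes (72%; Fisher's exact test, p = 0.0388), and the test did not pass in replicate 1 (p = 0.0822) or replicate 2 (p = 0.0668) alone.

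**Figure D4:**
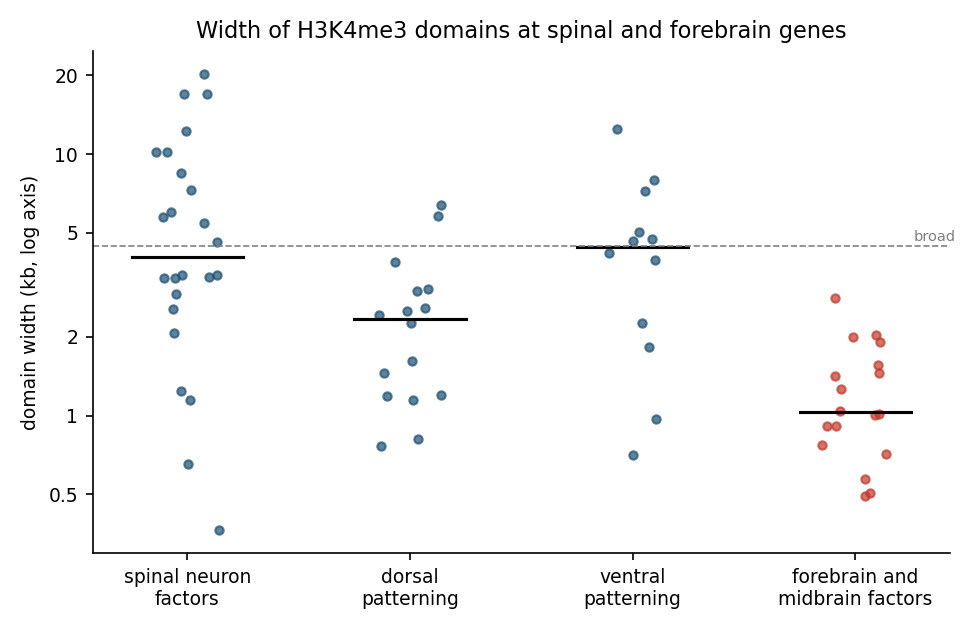
Width of the H3K4me3 domain at each marked gene (kb, log axis) in the 3 lists joined as spinal and in the forebrain and midbrain list; points are genes, horizontal bars are medians, and the dashed line is the width that defines a broad domain, 4446 bp. Of the 18 marked forebrain and midbrain genes, 0 reach the line.

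Hox genes of both groups of paralogues lay in broad domains, and the anterior group was not shown to be broad more often. Broad domains held 23 of 27 marked genes of paralogues 1 to 9 (85.2%) and 7 of 11 of paralogues 10 to 13 (63.6%), a difference of 21.5 percentage points that did not pass the test (two-sided Fisher's exact test, p = 0.195; p = 0.432 in replicate 1 and 0.221 in replicate 2). Many of these genes share a domain: the 27 anterior genes lay in 11 domains. The difference passed when only peaks with a signal of at least 5 were kept (43.0 points, exact test, p = 0.0106) and when broad meant the widest 1% (54.2 points, p = 0.00264). The anterior genes outside broad domains, chosen after their values were seen, were Hoxa4 (3518 bp), Hoxc4 (3223 bp), Hoxd1 (1864 bp) and Hoxb1 (1391 bp). Hoxb1, which acts in the hindbrain, had a signal of 4.51, against 62.4 at Hoxd3 and Hoxd4, which share the list's highest mean signal over the replicates (53.6 ± 8.77, SD, n = 2). The domain that holds an annotated start of both, shared with Hoxd8, Hoxd9 and the posterior gene Hoxd10, covers 16.8% of Hoxd3 and 35.5% of Hoxd4. Among the posterior genes, Hoxa10, Hoxc10 and Hoxd10 lay in domains shared with anterior genes. Hoxc10 had the highest mean signal (30.1 ± 23.3, SD, n = 2), from 13.7 in replicate 1, where Hoxa10 had 19.6, and 46.6 in replicate 2. In replicate 2 Hoxc5 and Hoxc9, anterior genes of the same domain, had the same 46.6, so the value is not particular to Hoxc10. In replicate 1 Hoxc5 had 13.7 and Hoxc9 had 18.3. Hoxd12 had no replicated peak. The marked posterior genes outside broad domains, chosen after their values were seen, were Hoxa13 (1297 bp), Hoxd13 (1018 bp), Hoxb13 (842 bp) and Hoxc13 (4255 bp), of which Hoxc13 was broad in both replicates' own peaks (4095 and 7199 bp).

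Signals at gene starts were higher in replicate 2 across most genes, by a factor that changed little with signal. Over the 14167 genes with a TSS peak in both replicates the median ratio of replicate 2 to replicate 1 was 1.47 (0.55 on the log2 scale), and 97.0% of the genes were higher in replicate 2. Each signal is relative to the controls of its own peak calling, so this ratio describes the scales of 2 deposited lists, not amounts of the mark, and it has no replicate check. The median log2 ratio was 0.56, 0.60, 0.57 and 0.51 in 4 equal groups of genes from low to high mean signal. Relative to the median of all genes, 20 of 22 gene lists with at least 3 genes lay within the central 95% of random lists matched on mean signal. The exceptions were the cardiac list, whose centred median of 6 genes was -0.50 on the log2 scale (percentile 1.39), and the housekeeping list at 0.14 (percentile 99.4). With width times signal in place of signal, 6 of 22 lists lay outside, led by Hox paralogues 1 to 9 at 0.86 and Hox paralogues 10 to 13 at 0.55. Many of these Hox genes share a domain. With each domain of replicate 2 counted once, an alternative chosen after the data were seen, the values were 0.43 over 11 domains and 0.51 over 8. Then 7 of 22 lists lay outside. Width times signal was summed over the unmerged peaks at a gene's TSS windows, so it depends on how each list splits a domain into peaks. Over Hoxb3 to Hoxb9 the domains were 77963 and 79072 bp wide in replicates 1 and 2. There replicate 2 had a single peak from 96269362 to 96331548, a stretch that replicate 1 split into shorter peaks. The common factor held for height, and these values do not test domain width.

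Single genes departed from the common factor. Among genes above the median signal, the log2 ratio was largest at Plxdc1 (2.08), Pnpla7 (2.03), Ptcd1 and Cpsf4, which share a domain (1.77 each), and Actrt3 (1.71). The domains of Pnpla7 and Actrt3 also held a TSS of Mrpl41 and of Mynn. At Plxdc1 the signal was 13.2 in replicate 1 and 55.9 in replicate 2, while the domain widths in the replicates had a mean of 4213 ± 220 bp (SD, n = 2). The ratio was smallest at Vps41 (-0.50), Plxna2 (-0.36), Dnajc24 (-0.35), Dcaf5 (-0.33) and Mtrf1l (-0.30). The pooled signal exceeded both replicates' own at Plxna2 (55.6 against 45.9 and 35.7), Dcaf5 (54.2 against 39.5 and 31.5) and Mtrf1l (50.9 against 39.3 and 31.9). It did not at Vps41 (26.4 against 37.7 and 26.6) or Dnajc24 (30.6 against 36.1 and 28.3). The low ratios at Plxna2, Dcaf5 and Mtrf1l may thus come from the deposited values and not from the genes. With 1 peak list per replicate these departures are values of the lists, with no test.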

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

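In this part, the tests on other tissues' genes, on the signal of forebrain genes, on housekeeping genes, with each domain counted once and on lists by width times signal were chosen after the results were seen. Width times signal itself was an alternative fixed before the data were examined. What was added is its count of lists outside the random range. Further values come from data that the comparisons left aside. Of the 920 broad domains, 46 had no protein-coding TSS within 1000 bp; 37 of these lay at noncoding genes and 9 at no annotated TSS. Among the replicated peaks, 21 lay on 12 unplaced or unlocalised contigs, with a median signal of 4.37. Of the pooled peaks, 4536 were absent from the replicated list, with a median signal of 3.09, and 110 of them overlapped peaks of both replicates.

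Broad domains at neural and Hox genes were weighed against features of the promoters and of the domain definition. Of the 10 lists, 9 stayed past the threshold against random lists matched on CpG density. Without merging of neighbouring peaks 8 stayed, and 10 stayed when each domain was counted once per list. These counts argue against CpG density near the TSS, merging and shared domains as the whole of the pattern. The CpG match covered only 500 bp either side of a TSS, so it cannot test how far CpG-rich sequence extends. A property of all tissue genes alike was tested on the 9 lists of other tissues, where 4 of 59 marked genes were broad, against 64 of 150 (42.7%, lower exact bound 34.6%) in the 10 nervous system lists. In replicate 2's own peaks and in the pooled peaks 7 of 62 genes of other tissues were broad, with an upper bound of 21.9%, the highest of the 4 peak lists. In each peak list the upper bound lay below the lower bound of the nervous system lists, which argues against a property of all these genes alike. The lists also differ in kind of gene: those of other tissues hold many genes of structural or secreted proteins, and several nervous system lists are mainly transcription factors. The counts therefore cannot exclude a property of developmental regulators of any tissue. The nervous system lists were not alike, with 2 of 16 dorsal patterning genes and 0 of 18 forebrain and midbrain genes broad, so what sets broad domains apart stays open; no biological explanation was tested.

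Wider domains at spinal genes than at forebrain transcription factors were weighed next. Spinal genes had the lower CpG density near the TSS (median 7.04 against 7.89 per 100 bp). With labels permuted only within 4 groups of CpG density the difference in median width kept a permutation p of 0.00293. That argues against CpG density near the TSS, and the extent of CpG-rich sequence was not tested. A single replicate as the source of the difference is argued against by the larger of the permutation p-values in the replicates' own peaks, 0.00875. Few cells from rostral brain in the dissected tissue might lower the signal of forebrain genes and narrow their peaks: their median signal was below that of spinal genes in both replicates (6.22 against 7.74 and 7.75 against 11.6), with permutation p of 0.146 in replicate 1 and 0.0287 in replicate 2 (0.0574 in the replicated peaks). The lower share of forebrain genes with a peak than in CpG-matched lists (72% against 93.3%, permutation, adjusted p = 0.00120) runs the same way. The labels do not state the dissected levels and the replicates fall on both sides of the threshold, so this stays open. The design holds 1 tissue, and no biological explanation was tested.

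Higher signal in replicate 2 was weighed against technical sources and tissue makeup. The median log2 ratio changed by -0.0482 from the lowest to the highest of 4 equal groups of genes by signal. A single scale factor for the library would give such a small change for height. With width times signal, 6 of 22 lists lay outside the central 95% of random lists, and 7 did with each domain counted once. That value is summed over unmerged peaks and depends on how each list splits a domain. It therefore cannot decide whether such a factor covers domain width. Another makeup of the tissue as the whole shift is argued against by housekeeping genes, active in every cell type: 20 of 20 were higher in replicate 2, with a lower quartile of 0.45 on the log2 scale. Beside the common shift, 2 of 22 lists lay outside the central 95% of random lists where chance gives 1.1 (exact interval of the share 1.12 to 29.2%), which met the bound of fewer than 3 written in advance but leaves smaller differences in makeup open; the explanation was split in 2 parts after that count was seen. The additional control file cannot be told apart from the library, since 97.0% of genes were higher in the replicate that used it and both replicates would have to be called against the same controls.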

How the results depend on the processing

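All alternatives here were fixed before the data were examined except basic transcripts, each domain once and the spinal set without secreted ligands, which were chosen after the result was seen. Lists with a call kept it in 146 of 150 tests of broad domains and in 108 of 117 tests of having a peak; lists without one stayed so, with the same sign, in 194 of 210 and 82 of 99.

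The share of peaks shared by the replicates moved with the strictness of the peaks. With -log10 q of at least 2, signal of at least 5, merged peaks, overlap of 50% of the peak and 50% of both peaks it was 93.2, 98.9, 89.4, 84.7 and 65.8% for replicate 1, and 76.2, 88.3, 84.4, 63.8 and 62.6% for replicate 2. Across shared peaks Pearson's r was 0.920 and Spearman's rho 0.906 at signal of at least 5, 0.936 and 0.938 with -log10 p, and 0.727 and 0.714 at the positions of replicate 1's peaks.

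Peaks at a TSS were 84.7% at signal of at least 5, 73.1 and 82.2% with windows of 500 and 2500 bp, 64.2 to 67.5% without a replicate, 67.7% in the pooled peaks and 71.8% with basic transcripts. Marked protein-coding genes were 63.5% at signal of at least 5, 65.8% with a window of 2500 bp, 64.9 to 65.9% without a replicate, 65.6% in the pooled peaks and 63.9% with basic transcripts.

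Against CpG-matched lists 1 list, the pan-neuronal one, passed the threshold upward in having a peak. The differences changed sign for the ventral patterning (-10.7 percentage points), spinal neuron (-4.32), Hox 10 to 13 (-5.26), forebrain and midbrain (-21.3, a call downward), neural crest (-6.95), erythroid (8.33) and epidermal lists (1.09). The forebrain and midbrain list also changed sign with a window of 500 bp (-0.505). Calls were gained in having a peak by mature glia with a window of 2500 bp (-32.5 points), without replicate 1 (-32.6) and in the pooled peaks (-32.3), and by Hox 10 to 13 in the same settings (34.2, 34.1 and 34.4). They were also gained by the cardiac (-42.1) and skeletal muscle lists (-30.2) at signal of at least 5, skeletal muscle with basic transcripts (-30.6), neural crest without replicate 2 (28.9) and ventral patterning in the pooled peaks (27.7).

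In broad domains, sign changes were confined to lists without a call, and housekeeping genes gained a call with the widest 10% (20.999 points). For mesenchyme the difference was -0.302 points at -log10 q of at least 2, -1.11 without merging, -1.48 with the widest 1% and -0.977 to 17.0 without a replicate. For endothelium it was -7.78 without merging, -0.589 with merging within 3000 bp and -1.48 with the widest 1%. For dorsal patterning it was -1.53 without merging, -1.48 with the widest 1% and -0.977 to 10.8 without a replicate. For housekeeping genes it was -1.41 at signal of at least 5 and -2.78 without merging. For the forebrain and midbrain list it was 3.38 with merging within 3000 bp, and for skeletal muscle 25.8 in the pooled peaks and -7.65 to 8.69 without a replicate.

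Spinal exceeded forebrain factors in having a peak by 20.2 and 17.0 points with windows of 500 and 2500 bp and by 12.5 to 15.2 without a replicate, past the threshold in none of these. In broad domains the difference was 21.2 points with the widest 1%. Without secreted ligands the differences were 18.6 points with a peak, 39.6 points in broad domains and 2389 bp in median width. The Hox difference was 43.0 points at signal of at least 5 and 54.2 with the widest 1%. The median log2 ratio of the replicates was 0.88 with -log10 p and 0.80 with width times signal. With width times signal 9 lists moved: Hox 1 to 9 to 0.86, Hox 10 to 13 to 0.55, mesenchyme to 0.39, neural crest to 0.33, spinal neuron factors to 0.27, dorsal patterning to 0.21, endothelium to 0.18, neural progenitors to 0.14 and chromatin regulators to -0.15.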

Other observations

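The genes named in this part were chosen after the results were seen, and no tests were made on them. Broad domains also covered the precursors of the neural microRNAs miR-9 and miR-124. The widest domain without a protein-coding TSS, on chromosome 13 from 83713227 to 83742972 (29746 bp), held Mir9-2. Mir9-1 lay in a domain of 16317 bp and Mir9-3 in one of 13663 bp, and Mir124a-1, Mir124a-2 and Mir124a-3 in domains of 9097, 16016 and 7006 bp. All 6 precursor genes were thus in broad domains, while 0 of 12 precursors of muscle, heart, liver and blood microRNAs, such as Mir1a-1, Mir122 and Mir142, lay in any domain. Of the 2195 annotated microRNA genes other than the 6, 45 (2.05%) lay in a broad domain. Precursors were scored at their own position, so a domain at a distant start of a host gene was not counted. No test is given, because 5 of the 6 lay in the widest domains without a protein-coding TSS, from which the group was picked.

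Families of transcription factors outside the fixed lists also lay in broad domains. In 10 families picked from the widest domains and from knowledge of neural development (Nr2f, Meis, Ebf, Pou3f, Zic, Nfi, Tshz, Bcl11, Onecut and Zfhx), 27 of 34 genes were broad, and 27 were broad in both replicates' own peaks. Zic1, Nfia and Nfib are also members of fixed lists. The exceptions were Nr2f6, Meis3, Ebf4, Zic5, Nfic, Onecut3 and Zfhx2. No test is given, because part of the families was picked for wide domains.

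Of the replicated peaks, 1175 overlapped no peak of replicate 1 and 63 no peak of replicate 2. The former were narrow, with a median width of 394 bp, and weak, with a median signal of 3.86.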
